A study of Arabidopsis thaliana with 4 samples.

How the data were processed

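Chromatin was immunoprecipitated from Arabidopsis thaliana seedlings aged 14 days, grown with 16 h of light at 21 °C and 8 h of dark at 19 °C and fixed with 1% formaldehyde, per the labels' protocols. Per the same protocols, chromatin was sheared to 250 to 500 bp, libraries were amplified with 18 PCR cycles from fragments of 270 to 300 bp, and single-end reads of 50 bp were sequenced. The 4 libraries were 1 of plants with TRB1 fused to green fluorescent protein on a GFP-binding matrix, 1 of wild-type plants on the same matrix, 1 of wild-type plants with an anti-TRB1 antibody and 1 of wild-type plants without it. Each group had 1 library. The design text of the series calls the 2 immunoprecipitation approaches biological replicates and mentions technical replicates, which could not be told apart in the lists.

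The submitters' processing notes name Bowtie2 version 2.2.2, SAMtools, bedtools and MACS, without their roles, and the builds TAIR9 and TAIR10. PePr, a caller for replicated libraries, is named only in the name of a deposited list. The thresholds, the control library of each call, the version of MACS and the build of each list are not given in the sources used here. The lists carry no header. The replicate 1 and replicate 2 lists hold a score per peak, which the authors deposited on a scale that is not given; it ran from 664 to 3233 in replicate 1 and from 87.6 to 3230 in replicate 2. The PePr list holds a p-value and an adjusted p-value per peak from the authors; the largest p-value in it is 1.0e-05 and the largest adjusted p-value 4.86e-05. Its other 2 value columns have no stated meaning and were not used. The genomic list holds positions only. Whether peaks were called on pooled libraries is not given for any list. Read depth per library is not given either, so a list with more peaks may come from a deeper library, a looser threshold or more binding.

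Peak positions are printed as the authors' lists give them, counted from 1. Genes came from a RefSeq gene table of another assembly release, TAIR10.1, which was used for names, classes and the placing of peaks relative to genes, and none of its coordinates are printed. It holds 27444 protein-coding genes on chromosomes 1 to 5, of which 10374 (37.8%) have a symbol, so lists found by name hold only part of their families. The table gives no strand, and no genome sequence was used here. For this reason both ends of a gene stood in for the transcription start, feature shares were taken over 4 classes by distance from gene ends, and the planned tests of the telomeric repeat motif and other motifs were not run. The peak score was compared at ribosomal protein genes in place of the planned comparison by motif.

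Peaks of different lists counted as overlapping from 1 bp. The expected overlap came from 1000 circular shifts (100 where sharing required 50% of both peaks), in which all peaks of a chromosome were moved by 1 random distance so that widths and spacing were kept; these permutation p-values were two-sided, with 0.000999 the smallest possible. Settings added for non-coding classes used 200 shifts, with 0.00498 the smallest possible. A gene had a peak when a peak overlapped the 500 bp on either side of 1 of its ends. Each of 16 gene lists was compared with all other nuclear protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 16 lists. Non-coding classes were compared by overlap with circular shifts, adjusted over 6 classes. Median scores were compared by 100000 permutations within 1 list. Exact (Clopper-Pearson) 95% intervals were used for shares, and a count of 0 was taken to allow 3 counts where no exact interval is given. Odds ratios were pooled over 10 strata of gene length and 4 of the gap to the nearest gene (Mantel-Haenszel). Gene families, taken as symbols with the same letters before a number, were tested where they had at least 10 members, which gave 177 families. Intervals are taken over counts of genes or peaks and cover counting error only. With 1 library per group they do not cover the spread between plants, and neighbouring genes can share a peak. Reads amplified by PCR without molecular identifiers are also not independent molecules.

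The comparisons, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the genes at the 10 genomic list peaks of highest mean rank in both replicate lists, up to 4 members of each gene list with peaks of highest rank (ties by position), and all telomere and TRB family genes. Genes named outside it are stated as such, and some genes that the rule names are not reported here. The gene lists were cytosolic and organellar ribosomal proteins, translation initiation factors, translation elongation and release factors, aminoacyl-tRNA synthetases, ribosome biogenesis, proteasome, histones, splicing, photosystem, chaperones, respiratory chain, MYB and bHLH factors, P450 enzymes, NLR proteins, and telomere and TRB family genes. Genes of other kinds taken in by the search words were found after the results were seen, and 9 lists were also tested without them; organellar ribosomal and NLR genes among them were also moved to their own lists. Alternatives covered the peak list, the higher-scoring 50% of peaks, the overlap rule, the distance to gene ends, the assignment of peaks to genes, the background genes and the null.

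Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The gene list test and the circular shift test were tried on simulated data. For lists of 52 genes the gene list test called 6.5% of 200 simulated lists with no enrichment, 70% at a fold of 2 and 99% at a fold of 3. For 4995 peaks the circular shift test called 4% of 100 simulations with no peaks moved to gene ends, 56% with a share of 0.05 moved and 100% with 0.2 moved. The overlap of 300 deposited replicate 1 peaks with the replicate 2 list was equal to that from a comparison of all pairs in 100% of peaks.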

Results

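TRB1 is a plant protein with a Myb-type DNA-binding domain that was known from its binding to telomeric repeats. Chromatin immunoprecipitation followed by sequencing was used to find where it lies along the chromosomes of Arabidopsis thaliana seedlings aged 14 days. There were 4 libraries in 4 groups, with 1 library in each group. In one approach a matrix that captures green fluorescent protein was applied to plants that made TRB1 fused to that protein under the TRB1 promoter, and wild-type plants treated with the same matrix were the control. In the other approach an antibody raised against TRB1 was applied to wild-type plants, and the control was wild-type chromatin without the antibody. The title of the series names genes of the translation machinery, and the comparisons concern where the peaks lay and which groups of genes had them.

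The values analysed were 4 peak lists rather than reads, so the read depth of each library is unknown, and the signal in the control libraries could not be set beside the peaks. The replicate 1 list held 3975 peaks with a median width of 2081 bp and covered 9.72 Mb of chromosomes 1 to 5. The replicate 2 list held 7480 peaks with a median width of 1728 bp and covered 15.3 Mb. A PePr list held 24219 peaks with a median width of 510 bp and covered 16.3 Mb, and a list of genomic peaks held 4995 intervals with a median width of 850 bp, which covered 4.72 Mb or 3.96% of the chromosomes. Which of the 2 immunoprecipitation approaches gave the replicate 1 list is not given in the sources used here. Each group had 1 library, so intervals and p-values describe counts of peaks or genes within these lists and not the spread between plants.

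Most regions of the replicate 1 list were found again by the other approach. Of its 3975 peaks, 3583 (90.1%) overlapped a replicate 2 peak, whereas 26.3% ± 1.80 (SD) did so when the peaks were shifted along their chromosomes. In the other direction 3664 of the 7480 replicate 2 peaks (49.0%) overlapped a replicate 1 peak, against 14.6% ± 1.01 (SD) after shifting. Both shares exceeded those of all 1000 shifts, 3.43-fold and 3.35-fold over their means (two-sided shift permutation p = 0.000999 for each, the smallest that 1000 shifts can give). With stricter rules the contrast was larger: 67.2% of replicate 1 peaks had a replicate 2 centre within 200 bp of their own, 26.6-fold over the shifted mean, and 84.5% shared at least 50% of both peaks with a replicate 2 peak, 9.19-fold over it (from 100 shifts, permutation p = 0.00990, the smallest they can give). Among the 50% of peaks with the higher scores in each list, 77.5% of replicate 1 peaks overlapped, 5.22-fold over the shifted mean.

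Peaks found by both approaches had higher scores than peaks found by 1. In the authors' deposited replicate 1 list the median score was 1917 for the 3583 shared peaks and 1181 for the 392 others, and in the replicate 2 list it was 1374 for the 3664 shared peaks and 296 for the 3816 others (permutation p = 2e-05 for each list, two-sided, the smallest that the resamples can give). These scores are the authors' own, on a scale that is not given, and were compared only within a list. Across the 3583 shared peaks the ranks of the scores in both lists were correlated with Spearman's rho of 0.377; peaks are not independent replicates. In the authors' deposited lists a score of 3100 was shared by 1124 replicate 1 peaks (28.3%) and 876 replicate 2 peaks (11.7%), so the order of peaks at or above that score carries little information.

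The list of genomic peaks was the part of the chromosomes that the other 3 lists had in common. Each of its 4995 intervals was identical to a stretch shared by the replicate 1, replicate 2 and PePr lists, and no such stretch was missing from it. Of these intervals, 4062 were whole PePr peaks and 933 were trimmed, with 411 of them narrower than the narrowest PePr peak of 340 bp. The genomic list is therefore not independent of the others, and the replication is that of the replicate 1 and replicate 2 lists.

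The peaks gathered at the ends of protein-coding genes. Of the 4995 genomic list peaks, 67.9% had their centre within 500 bp of a gene end, against 35.4% ± 1.56 (SD) after shifting, which is 1.92-fold (two-sided shift permutation p = 0.000999, the smallest possible). The share was 67.1% in the replicate 1 list, 70.6% in the replicate 2 list and 64.1% in the PePr list. Within 200 bp of a gene end lay 40.5% of the centres, 2.52-fold over shifting, and within 1000 bp 87.5%, 1.50-fold. The strand of the genes was not used here, so starts and ends of genes were not told apart and promoters were not measured as such.

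Gene bodies away from the ends held few of the peaks, and so did the space far from genes. Centres inside a gene and within 500 bp of an end made up 42.7% of the genomic list, against 22.1% ± 1.24 (SD) after shifting, and centres outside genes but within 500 bp made up 25.2%, against 13.3% ± 0.572. Centres inside a gene and farther from its ends made up 18.7%, 0.581 times the shifted mean of 32.1%. Centres outside genes and farther away made up 13.5%, 0.414 times the shifted mean of 32.5%. Each of these 4 shares lay outside all 1000 shifts (two-sided shift permutation p = 0.000999, the smallest possible). Shifting did not keep peaks in the same part of a chromosome, so an uneven spread of genes along it also enters these folds.

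**Figure D1:**
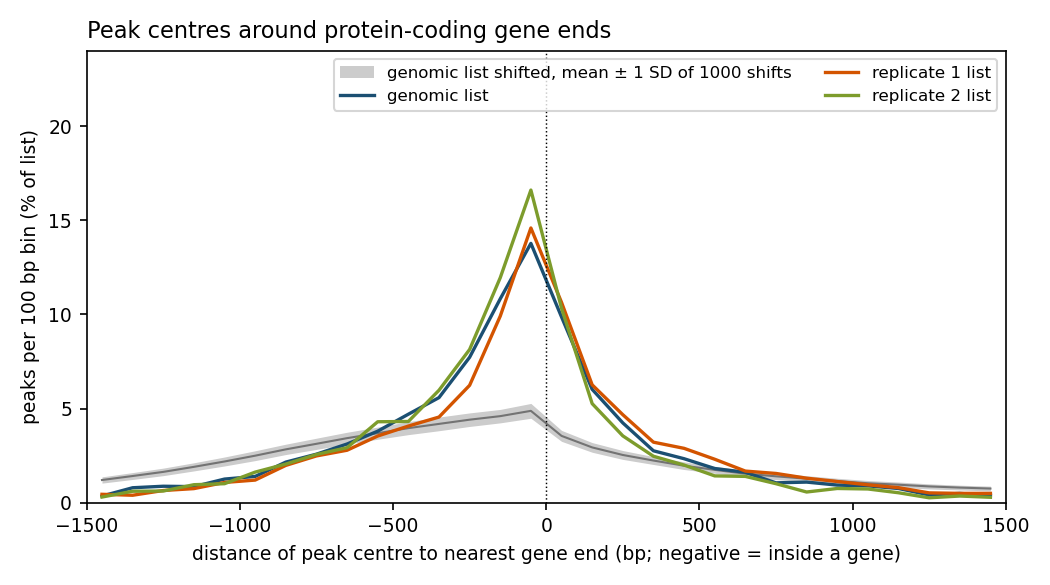
Peak centres by distance to the nearest protein-coding gene end, in bins of 100 bp, as a percentage of the peaks of each list; negative distances (bp) lie inside a gene, and the grey band is the mean ± 1 SD of 1000 circular shifts of the genomic list. The highest bin of all 3 lists is the 100 bp just inside a gene end, with 13.8% of the genomic list, 14.6% of the replicate 1 list and 16.6% of the replicate 2 list, against 4.88% after shifting.

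The peaks of highest rank lay at genes of several kinds. Ranked by their scores in both replicate lists, the first 10 genomic list peaks included those at NOP56, a core protein of the box C/D small nucleolar ribonucleoprotein (chromosome 1, 20986501 to 20987350), and at AGL65, a MADS-box transcription factor (chromosome 1, 6466121 to 6466970). The others near gene ends were at AT1G77730 (chromosome 1, 29213991 to 29215180), AT4G10820 (chromosome 4, 6648191 to 6649040), AT3G53680 (chromosome 3, 19897481 to 19898160) and AT1G30190 (chromosome 1, 10618541 to 10619900). The remaining 4 had no gene end within 500 bp of them, and lay at 11860391 to 11862090, 9344561 to 9346090 and 7450931 to 7451610 of chromosome 3 and at 7172981 to 7174716 of chromosome 4. In the authors' deposited lists the peak at NOP56 had a score of 3127 in replicate 1 and 3100 in replicate 2, and its PePr p-value was 2.6e-18. Each of the 10 peaks had a score of 3100 or more in both lists, the range where the order of peaks carries little information. They are therefore not read as the strongest peaks.

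Genes of cytosolic ribosomal proteins, the structural proteins of the ribosomes that translate nuclear messages, had a peak far more often than other genes. The list under this name held 52 genes, of which 15 proved to be of other kinds; of the 37 left, 25 (67.6%) had a genomic list peak within 500 bp of an end, 3.45-fold over other genes (adjusted exact p = 5.00e-09). Of all 52 listed genes, which stand for the group in what follows unless stated, 31 (59.6%, exact 95% interval 45.1 to 73.0) had a genomic list peak within 500 bp of an end, against 19.6% of other genes, a 3.05-fold difference. Examples were RPS15 (chromosome 1, 1139851 to 1141720), SAC52, which encodes the large-subunit protein RPL10A (chromosome 1, 4887331 to 4888520), PFL, which encodes the small-subunit protein RPS18A (chromosome 1, 8067351 to 8068200), and RPL3B (chromosome 1, 22722881 to 22723560). All 4 peaks had a score of 3100 in both of the authors' deposited replicate lists, and their PePr p-values ran from 1.7e-26 at PFL to 4.9e-07 at RPL3B. The odds ratio was 6.07 (95% interval 3.37 to 11.1), with an adjusted p of 4.33e-09 in Fisher's exact test (two-sided, Benjamini-Hochberg over 16 lists).

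The same list stood out with each approach alone. In the replicate 1 list 32 of the 52 listed genes had a peak (2.51-fold, adjusted exact p = 2.70e-07), and in the replicate 2 list 44 of them did (2.05-fold, adjusted exact p = 3.09e-09). In the PePr list 49 had a peak (1.37-fold, adjusted exact p = 0.000232). That list reached 68.7% of all protein-coding genes, so no fold could be large there; the odds ratio was 7.47 (95% interval 2.41 to 37.5). Among the 50% of genomic list peaks with the higher scores the fold was 4.75 (adjusted exact p = 2.06e-11). When peaks were shifted along the chromosomes in place of the Fisher test, the adjusted permutation p was 0.0160 at a fold of 3.05. The 15 genes of other kinds that the search words had taken in were ribosomal proteins of chloroplasts and mitochondria and disease resistance genes with similar symbols, and 6 of these had a peak.

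Translation initiation factors also had peaks more often than other genes. Peaks of the genomic list lay at 15 of 29 (51.7%, exact 95% interval 32.5 to 70.6), 2.64-fold over other genes, with an odds ratio of 4.39 (1.98 to 9.83) and an adjusted exact p of 0.000908. They included TIF3H1 and EIF3G1, subunits h and g of initiation factor eIF3 (chromosome 1, 3610121 to 3611140, and chromosome 3, 3580031 to 3580710). The others of highest rank were eIF6A, of a factor that keeps ribosomal subunits apart (chromosome 3, 20633751 to 20634600), and the RNA helicase EIF4A1 (chromosome 3, 4594251 to 4595440). In the replicate 1 list 16 had a peak (adjusted exact p = 0.00545) and in the replicate 2 list 22 (adjusted exact p = 0.00115), and with the PePr list the fold was 1.31 and the odds ratio 3.96 (adjusted exact p = 0.0337). Shifting the peaks gave an adjusted permutation p of 0.0240; with genes that had close neighbours on both sides left out, 5 of 12 had a peak and the adjusted exact p was 0.183, at a fold of 2.42.

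Genes of ribosome biogenesis and the nucleolus, where ribosomal subunits are assembled, had peaks at 8 of 14 (57.1%, exact 95% interval 28.9 to 82.3), 2.91-fold over other genes, with an adjusted exact p of 0.0113. Besides NOP56 these included FIB1, the fibrillarin that methylates ribosomal RNA (chromosome 5, 21293011 to 21294540), NUC-L1, a nucleolin (chromosome 1, 18097691 to 18098540), and the pescadillo-related gene AT5G14520 (chromosome 5, 4684011 to 4684860). In the replicate 1 list 9 had a peak (adjusted exact p = 0.0101) and in the replicate 2 list 13 (adjusted exact p = 0.000721), and in the PePr list all 14 did, at a fold of 1.46, the highest possible there (adjusted exact p = 0.0248). This call was lost when the peaks were shifted along the chromosomes (2.58-fold, adjusted permutation p = 0.133) and when genes with close neighbours on both sides were left out (3 of 7 with a peak, 2.49-fold, adjusted exact p = 0.277). Of the 14 listed genes, 1 proved to be of another kind and had no genomic list peak. Without it 8 of 13 had a peak (3.14-fold, adjusted exact p = 0.00585). The counts given for the replicate and PePr lists are of all 14.

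**Figure D2:**
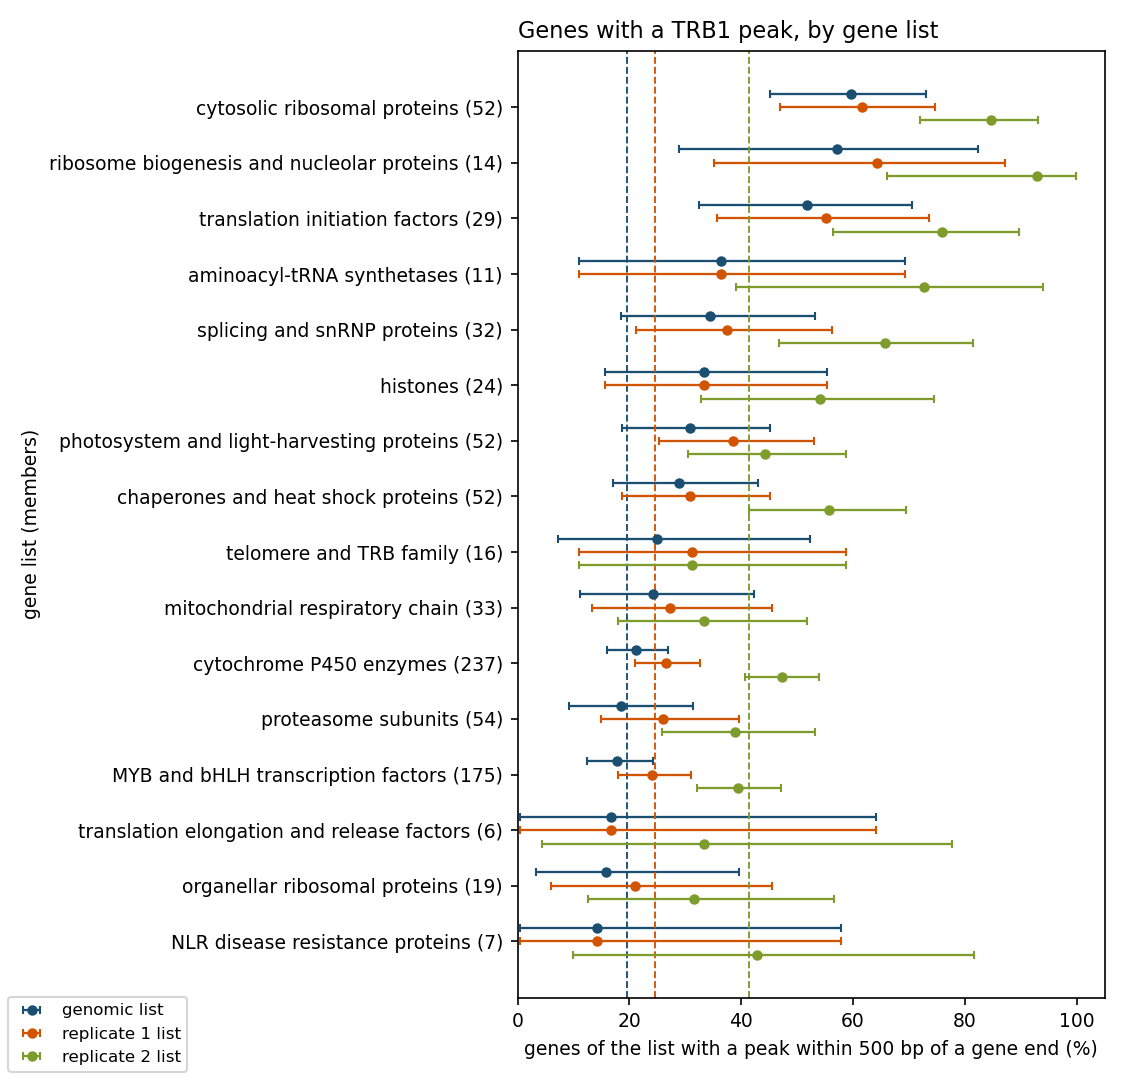
Percentage of the genes of each list with a peak within 500 bp of a gene end, for the genomic, replicate 1 and replicate 2 lists; bars are exact 95% intervals, vertical dashed lines give all protein-coding genes, and numbers after the names are members. The 52 genes listed as cytosolic ribosomal proteins, 15 of them of other kinds, reach 59.6%, 61.5% and 84.6%, against 19.6%, 24.6% and 41.4% of all genes.

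Other genes of protein synthesis did not pass the test in the genomic list. Organellar ribosomal proteins had a peak at 3 of 19 genes (PSRP3/2 and RPS14 among them), 0.804 times the share of other genes, and translation elongation and release factors at 1 of 6 (ERF1-2, a release factor), with an adjusted exact p of 1 for both. With the higher-scoring 50% of peaks the organellar fold was 0.496, and with peaks that overlap the gene 0.306, neither past the threshold (adjusted exact p = 0.943 and 0.409). Of 11 genes listed as aminoacyl-tRNA synthetases, which charge transfer RNAs, 4 had a peak (1.85-fold, adjusted exact p = 0.487): OVA5, ATKRS-1, EDD1 and RNL, the last of which is a tRNA ligase and no synthetase. The organellar list missed 11 chloroplast or mitochondrial ribosomal protein genes that stood among the cytosolic ones, 5 of them with a peak; with these moved in, the direction turned, at 8 of 30 genes (26.7%, 1.36-fold, adjusted exact p = 0.616). With 6 to 19 members these lists could show only large differences. The exact 95% interval of the elongation and release factors, for instance, ran from 0.421% to 64.1%.

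Splicing and snRNP proteins, which remove introns, had a peak at 11 of 32 genes (34.4%, 1.75-fold, adjusted exact p = 0.171), led by SR34, SmD3, U1A and RUXF; without 4 members of other kinds it was 10 of 28. The splicing list passed with the replicate 2 list (1.59-fold, adjusted exact p = 0.0264) and with the PePr list (1.41-fold, adjusted exact p = 0.00129). Histones had a peak at 8 of 24 genes (1.70-fold, adjusted exact p = 0.269), among them GAMMA-H2AX, HTB2, HON4 and HTA8, and passed when each peak was given only to the gene with the nearest end (2.45-fold, adjusted exact p = 0.0459). Photosystem and light-harvesting proteins, which capture light in chloroplasts, had a peak at 16 of 52 genes (30.8%, 1.57-fold, adjusted exact p = 0.171). Without 2 members of other kinds it was 16 of 50. The genes with a peak included LHCA3, PSAK, and CAB3 and CAB2, which shared 1 peak (chromosome 1, 10472171 to 10474550). The photosystem list passed with the PePr list (1.23-fold, adjusted exact p = 0.0292) and when genes with close neighbours on both sides were left out (12 of 27, 2.59-fold, adjusted exact p = 0.00718).

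Chaperones and heat shock proteins had a peak at 15 of 52 genes (1.47-fold, adjusted exact p = 0.269), among them HSP23.6-MITO, HSC70-1, CPN10 and HSPRO2. The last is no chaperone, and 6 members of that list were of other kinds, chiefly copper chaperones; of the 46 left, 12 had a peak. Proteasome subunits had one at 10 of 54 (0.943 times other genes, adjusted exact p = 1), with RPN1B, RPT2, RPT2b and RPT1A of highest rank. The gene RPT2 is ROOT PHOTOTROPISM 2 and no proteasome gene, and 16 members of that list were of other kinds, chiefly poly(A)-binding proteins; of the 38 left, 5 had a peak. Both lists passed with the PePr list, at 1.26-fold (adjusted exact p = 0.0222) and 1.24-fold (adjusted exact p = 0.0248), which for the proteasome is the opposite direction.

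Among lists not tied to protein synthesis or folding, no list passed in the genomic list. The mitochondrial respiratory chain had a peak at 8 of 33 genes (COX19-2, SDH3-1, SDH2-3 and the chloroplast NDH subunit NdhS among them), at 1.23-fold; without 8 members of other kinds it was 7 of 25. Cytochrome P450 enzymes had one at 50 of 237 (CYP704A1, CYP86A4, CYP86A8 and CYP709B2 leading), at 1.07-fold. MYB and bHLH transcription factors had one at 31 of 175 (AT3G11280, MYB15, LAF1 and AT5G47390 leading), at 0.901 times other genes. The adjusted exact p was 0.757 for each of these 3. Disease resistance genes of the NLR class had a peak at 1 of 7 (adjusted exact p = 1), and with 1 gene of another kind removed and 4 moved in from the ribosomal list at 2 of 10 (1.02-fold).

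Ribosomal protein genes were set directly against the other lists by Fisher's exact test (two-sided, adjusted over 15 comparisons). They had a peak more often than proteasome genes (adjusted exact p = 0.000104), organellar ribosomal protein genes (0.00456), respiratory chain genes (0.00533), chaperone genes (0.00717) and photosystem genes (0.0119). The same held against MYB and bHLH genes (2.81e-07), P450 genes (8.32e-07) and telomere genes (0.0411). A difference was not shown from initiation factors (0.686), biogenesis genes (1), synthetases (0.223), elongation and release factors (0.100), splicing genes (0.0636), NLR genes (0.0636) or histones (0.0656). Several of the lists held genes of other kinds; with genes of other kinds removed and organellar ribosomal and NLR genes moved to their own lists, the difference from organellar ribosomal protein genes (25 of 37 against 8 of 30) had an adjusted exact p of 0.00327. Differences then also passed against NLR genes (adjusted exact p = 0.0185), splicing genes (0.0201), histones (0.0233) and elongation and release factors (0.0355), and still not against synthetases (0.0759), initiation factors (0.230) or biogenesis genes (0.741). Among genes without close neighbours on both sides, 10 of 18 ribosomal protein genes (55.6%) and 12 of 27 photosystem genes (44.4%) had a peak, and these did not differ detectably (exact p = 0.550).

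The approaches were also compared gene by gene. In all, 6746 of 27444 protein-coding genes had a peak in the replicate 1 list and 11362 in the replicate 2 list, with 6109 in both. Of the ribosomal protein genes none had a peak only in replicate 1 and 12 had one only in replicate 2, a ratio that did not differ from that of other genes (Fisher's exact p = 0.631). No list differed between the approaches in this test (adjusted exact p = 1 for all 16 lists). It had little power, since most lists had few genes with a peak in 1 replicate list only. Of genes outside the ribosomal list, 637 had a peak only in replicate 1 and 5241 only in replicate 2. The lack of a difference is therefore not read as equality of the approaches.

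Peaks of the replicate 2 list that the other approach also found lay near ribosomal protein genes more often than those it did not find, 29 of 3664 (0.791%) against 14 of 3816 (0.367%), a 2.16-fold difference (Fisher's exact p = 0.0207, two-sided). Within the 50% of replicate 2 peaks with the lower scores this was 1 of 955 against 6 of 2785, the opposite direction (0.486-fold, exact p = 0.686). In the replicate 1 list 26 of 3583 shared peaks (0.726%) and 0 of 392 others lay near such a gene; the latter allows a share of up to 0.765%, and the difference did not pass (exact p = 0.104). It passed when sharing required 50% of both peaks (0 of 615 others, exact p = 0.0251), a count of 0 that allows up to 0.488%. Such limits cover counting error only.

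Peaks near ribosomal protein genes also had high scores in the replicate 2 list. The median score in the authors' deposited replicate 2 list was 2819 for 43 peaks near these genes and 567 for the other 7437 (permutation p = 2e-05, two-sided, the smallest that the resamples can give). In the authors' deposited replicate 1 list the medians were 2348 for 26 peaks and 1763 for the other 3949, a difference that did not pass (permutation p = 0.255).

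Genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, overlapped peaks more than any other non-coding class tested. Of 287 snoRNA genes, 119 (41.5%, exact 95% interval 35.7 to 47.4) overlapped a genomic list peak, against 4.47% ± 1.84 (SD) after shifting, 9.27-fold. Transfer RNA genes overlapped at 93 of 625 (14.9%), against 4.35% ± 1.03, 3.42-fold, and long non-coding RNA genes at 301 of 3480 (8.65%), against 5.85% ± 0.466, 1.48-fold. Pseudogenes overlapped at 100 of 4843 (2.06%), 0.200 times the shifted mean of 10.3% ± 1.78. Each of these 4 had an adjusted permutation p of 0.00150, from 1000 shifts (two-sided, adjusted over 6 classes). The folds differed between lists: with replicate 2 alone the snoRNA fold was 5.33 and the transfer RNA fold 1.72, and the snoRNA fold was 3.22 with the PePr list and 14.2 with the higher-scoring 50% of peaks, all still past the threshold. Small nuclear RNA genes (8 of 82, 2.03-fold, adjusted permutation p = 0.0587) and microRNA genes (23 of 326, 1.49-fold, adjusted permutation p = 0.0729) did not pass. The pseudogene class was taken as RefSeq names it. How well reads of 50 bp can be placed in pseudogenes was not measured. Shifting also did not keep peaks in the same part of a chromosome, so where pseudogenes lie along it enters the fold. Fewer peaks in pseudogenes than after shifting need therefore not mean less binding.

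Many of these genes lie next to protein-coding genes or to each other, so loci were also compared with positions at equal distances from random protein-coding gene ends. Then snoRNA loci overlapped peaks at 72 of 142 (50.7%), 6.30-fold over the matched mean of 8.05% ± 2.29 (SD), and transfer RNA loci at 93 of 494 (18.8%), 2.18-fold over 8.63% ± 1.4. The excess of long non-coding RNA genes was not seen with this matching (0.976-fold, adjusted permutation p = 0.890), and pseudogenes stayed low (0.165-fold). The snRNA call depended on the list, passing with replicate 2 (2.84-fold, adjusted permutation p = 0.00498) and with the PePr list (2.78-fold, adjusted permutation p = 0.00597). The microRNA call passed with replicate 1 (1.51-fold, adjusted permutation p = 0.0239) and with replicate 2 (1.49-fold, adjusted permutation p = 0.00498). No excess of microRNA genes was seen with the PePr list (1.02-fold, adjusted permutation p = 0.910) or with matching (1.02-fold, adjusted permutation p = 1).

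**Figure D3:**
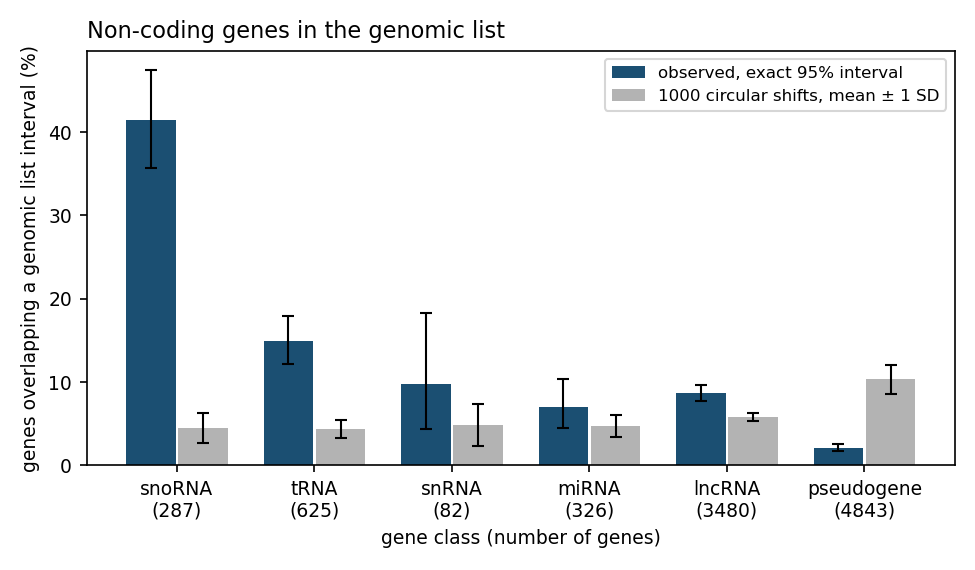
Percentage of the genes of each non-coding class that overlap a genomic list interval (dark bars, with exact 95% intervals) beside the mean ± 1 SD of 1000 circular shifts (grey bars); numbers under the names are genes. Small nucleolar RNA genes reach 41.5% against 4.47%, and pseudogenes lie at 2.06% against 10.3%.

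Genes of telomere maintenance and of the TRB family itself did not stand out, with a genomic list peak at 4 of 16 (25%, exact 95% interval 7.27 to 52.4, adjusted exact p = 0.757). The 4 were STN1, a subunit of the complex that protects chromosome ends (chromosome 1, 2187221 to 2188070), TRP1, a telomeric repeat binding protein (chromosome 5, 23967111 to 23967450), and the TRB family genes AT1G17520 (chromosome 1, 6023951 to 6024630) and AT1G72740 (chromosome 1, 27383091 to 27383770). At KU70, MDO1, TRB3, CTC1, AtPOT1b and TRB2 there was a PePr peak only, and KU80, AtPOT1a, TRFL1, TBP1 and TERT had no peak in any list. At TRB1 itself the replicate 1 list had a peak of 7682 bp (chromosome 1, 18493040 to 18500721) and the replicate 2 list 1 at 18496109 to 18497881, but there was no PePr peak, so the gene is not in the genomic list. In the authors' deposited lists both peaks at TRB1 had a score of 3100, and 15 of the 3975 replicate 1 peaks were wider. Plants that made the fusion protein carried a TRB1 fusion gene that their wild-type control lacked. Whether reads of that gene gave 1 of these peaks was not tested, and which list came from those plants is not given. The peaks are therefore not read as binding of TRB1 to its own gene.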

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

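The test of photosystem genes, the removal of close neighbours and the split of PePr peaks were chosen only after the result was seen. The tests in each replicate list were chosen in advance, but what an artefact of 1 approach would show in them was written down only after the result was seen. A large part of the PePr list lay outside the genomic list and drew attention as signal that the main comparisons leave out: 13910 of its 24219 peaks (57.4%) overlapped no peak of either replicate list. Of these, 61.0% had their centre within 500 bp of a gene end, against 35.4% ± 1.16 (SD) after shifting, so they lay at gene ends well above what shifting gave (shift permutation p = 0.00498, the smallest that 200 shifts can give). Near ribosomal protein genes lay 12 of them (0.0863%, exact 95% interval 0.0446 to 0.151), against 30 of the 4980 PePr peaks found in both replicate lists (0.602%, 0.407 to 0.859). PePr peaks that overlapped the replicate 2 list alone numbered 4441, with 72.3% near gene ends and 0.338% near ribosomal protein genes, and those that overlapped the replicate 1 list alone numbered 888, with 52.7% near gene ends and 0 near ribosomal protein genes (exact 95% interval up to 0.415%). In the replicate 2 list 44 of the 52 listed ribosomal protein genes had a peak near an end. PePr peaks that overlap such a peak are kept out of the group found in neither list by definition. Median widths also differed, at 510 bp in that group and 850 bp in the group found in both. The shares near ribosomal protein genes are therefore not read as a difference between kinds of peaks.

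The excess of peaks at cytosolic ribosomal protein genes was weighed against 3 technical explanations. These genes had a median length of 1616 bp, against 2078 bp for all protein-coding genes, but within strata of gene length and spacing the pooled odds ratio kept a lower 95% bound of 3.0, which argues against length and spacing as the whole cause. An artefact of 1 approach is argued against by the replicate lists, the larger of whose adjusted exact p-values was 2.70e-07. Signal at highly expressed genes in general stays open: photosystem genes had peaks less often than ribosomal protein genes (exact p = 0.00554), but these data hold no expression values, and without genes that have close neighbours on both sides the lists did not differ detectably (exact p = 0.550). No biological explanation was tested, since no group of the design changed translation.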

How the results depend on the processing

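Overlap with the gene or 1000 bp around it, the exclusion of close neighbours, the pooling by gene length, list clean-up and moved members, narrow intervals, feature shares in other lists, and the matching, loci and windows of non-coding classes were chosen only after the result was seen. Limits were the unknown depth of each library, the lack of strand, 1 library per group and lists of 6 to 237 genes. Of 275 alternatives to 30 results, 225 kept direction and side of the threshold, 15 passed where the original had not, 3 no longer passed, 31 reversed and 1 moved. The overlap of the replicate lists stayed between 3.43-fold and 26.6-fold, the share near gene ends between 1.50-fold and 2.52-fold, cytosolic ribosomal proteins between 1.37-fold and 4.75-fold, snoRNA genes between 3.22-fold and 14.2-fold, transfer RNA genes between 1.72-fold and 4.10-fold, and pseudogenes between 0.165-fold and 0.233-fold, all past the threshold. Of 44 settings chosen in advance, 20 were not run, all on motifs. No paired analysis was possible because only peak lists were analysed here, which hold no values per library.

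Folds under each setting follow, and the cause was not tested except where stated. When sharing required 50% of both peaks, 31.1% of genomic list intervals were found in every other list, since they are narrower than the replicate peaks. With 1 replicate left out in turn, folds ran from 0.939 to 1.05 for the proteasome, 1.53 to 1.59 for splicing, 0.805 to 1.11 for the respiratory chain, 0.581 to 1.04 for NLR genes, 0.755 to 1.27 for telomere genes, 1.49 to 2.84 for snRNA and 1.49 to 1.51 for microRNA genes. With replicate 1 peaks that overlap replicate 2, proteasome genes were at 1.05, MYB and bHLH genes at 1.02 and microRNA genes at 1.57 (now passing). With the PePr list, reversals were 1.07 for organellar ribosomal proteins, 1.46 for elongation and release factors, 1.24 for the proteasome, 0.977 for P450 enzymes, 1.04 for NLR genes and 0.910 for telomere genes. Splicing (1.41), photosystem (1.23), chaperone (1.26) and snRNA genes (2.78) then passed, and microRNA genes were at 1.02.

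With the higher-scoring 50% of peaks, reversals were 1.57 for elongation and release factors, 0.857 for synthetases, 1.05 for the proteasome, 0.955 for P450 enzymes, 1.35 for NLR genes and 0 for telomere genes, and splicing passed at 2.66. With the nearest gene end only, elongation and release factors were at 1.22, NLR genes at 1.05 and telomere genes at 0.916, and histones passed at 2.45. With peaks required to overlap the gene, P450 enzymes were at 0.983 and telomere genes at 0.728; with 1000 bp added on either side, MYB and bHLH genes were at 1.01. With genes that have close neighbours on both sides left out, initiation factors (2.42, adjusted exact p = 0.183) and biogenesis genes (2.49, adjusted exact p = 0.277) no longer passed, with fewer genes tested, photosystem genes passed at 2.59, and the proteasome (1.29), respiratory chain (0.893) and MYB and bHLH genes (1.11) reversed. With genes moved in from the cytosolic ribosomal list, organellar ribosomal proteins (1.36) and NLR genes (1.02) reversed, through their changed membership. With circular shifts, biogenesis genes no longer passed (2.58, adjusted permutation p = 0.133). Among lower-scoring replicate 2 peaks the shared against single ratio near ribosomal protein genes was 0.486. With equal windows snRNA (2.38) and microRNA genes (1.55) passed, as did microRNA loci (1.52), and long non-coding RNA genes matched to gene ends were at 0.976.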

Other observations

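The search over 177 gene families, the families named here, the genes of smallest PePr p-value and the comparison of snoRNA genes between lists were chosen only after results were seen. The depleted family with the smallest p-value was that of LCR genes, most of which encode small cysteine-rich proteins related to defensins (AT1G27340, an F-box gene, shares the symbol). None of 81 had a genomic list peak, which allows up to 3.70%, against 19.6% of all genes (exact adjusted p = 4.74e-06 over 177 families). Single lists did hold peaks at some of them, 6 in replicate 1, 6 in replicate 2 and 27 in the PePr list. Their median length was 585 bp, and 19.2% of the 18436 other genes in their wide range of lengths, 274 to 2742 bp, had a genomic list peak (exact p = 4.47e-08). Within strata of gene length and spacing the Mantel-Haenszel chi-square p was 0.00118; neither p was adjusted over the families. With 81 members the family is large; smaller families such as ABCI (18 genes) and PUP (19 genes) also had no peak and did not pass.

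Genes of the CHX family, cation exchangers that move ions and protons across membranes, had a genomic list peak at 16 of 28 (57.1%, 2.91-fold, exact adjusted p = 0.00114 over 177 families). They were CHX14, CHX6B, CHX6A, ATCHX5, ATCHX1, CHX16, CHX2, CHX19, CHX4, CHX12, CHX10, CHX17, CHX3, CHX9, CHX24 and CHX25. In the replicate 1 list 17 had a peak (2.47-fold) and in the replicate 2 list 21 (1.81-fold); in the PePr list 24 did, which is no longer past the threshold (1.25-fold, adjusted exact p = 0.381). Translation families passed in the same search: 13 of 21 EIF genes (adjusted exact p = 0.00155), 13 of 24 RPS genes (0.00788) and 12 of 23 RPL genes (0.0177). JAZ genes, which encode repressors of jasmonate signalling, had a peak at 6 of 10 (JAZ1, JAZ3, JAZ5, JAZ6, JAZ10 and JAZ12), and ECT genes, which encode readers of methylated RNA, at 6 of 11. Neither passed (adjusted exact p = 0.146 and 0.209).

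The CHX pattern was weighed against the clustering of its genes, since several copies lie side by side. With copies within 5000 bp of each other merged, 11 of 20 loci had a peak (exact p = 0.000474 against other genes), which argues against 1 peak having been counted for several copies. Among the 15 copies with no other copy within that distance 8 had a peak (exact p = 0.00374), which argues against reads shared between neighbouring copies; reads shared with distant copies were not tested. Of other genes in the CHX range of lengths 21.2% had a peak (exact p = 3.76e-05), so length alone did not account for the excess. That TRB1 may lie at CHX genes for a biological reason is a hypothesis found and tested on the same lists, and no biological explanation was tested.

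The snoRNA pattern was weighed against the peaks of neighbouring protein-coding genes. The share of snoRNA loci in peaks lay 18.7 SD above the mean of positions at equal distances from random protein-coding gene ends, which argues against an ordinary neighbouring gene end as the cause. Hosts or neighbours that are themselves translation genes were not separated from other genes, so that source of signal could still account for part of it. Signal at highly expressed genes in general also stays open for snoRNA and transfer RNA genes, since these data hold no expression values. No biological explanation was tested.

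Of the same 287 snoRNA genes, 64.8% overlapped a replicate 1 peak, 75.6% a replicate 2 peak and 51.2% a PePr peak (replicate 2 against PePr, exact McNemar p = 5.62e-14). With every peak replaced by 500 bp on either side of its centre the shares were 39.7%, 49.5% and 62.4%, and the order of replicate 2 and PePr was reversed (exact McNemar p = 4.34e-07). These shares were not set against what the number of peaks gives, 7480 in the replicate 2 list and 24219 in the PePr list. Neighbouring snoRNA genes are also not independent, so neither order is read as a difference in binding. The genes at the smallest PePr p-values in the authors' deposited list were TIM17-1, of the mitochondrial protein import machinery (2.7e-101), PUM9, a Pumilio RNA-binding protein (2.0e-77), ACA.l (3.8e-77) and AT2G02890 (1.4e-73).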
